A study of Hansenula anomala with 15 samples.

How the data were processed

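The samples were whole fermentation broth of Wickerhamomyces anomalus taken at 0, 16, 32, 48 and 64 h, with 3 biological replicates at each time point per the labels. Per the labels, total RNA was extracted with TRIzol, checked by NanoDrop and Bioanalyzer, and made into polyA libraries with the VAHTS Universal V6 kit. The authors' processing notes name fastp, HISAT2 and HTSeq without versions or further detail. The deposited table holds raw counts per gene, which are whole numbers and were not normalised by the authors. The genome build is not given in the sources used here. All 6571 identifiers in the table (6417 protein-coding and 154 tRNA genes) are locus tags of the RefSeq assembly Wican1, and gene lengths and part of the names were taken from its annotation. The deposited annotation and RefSeq together gave 3433 genes a symbol and 4017 a KOG description. Symbols rest on homology, and no genome sequence was used, so reads shared between near-identical paralogs could not be assessed. No coordinates are printed, since the build behind the counts is not stated.

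Totals ranged from 17.6 to 40.1 M counts per library, and between 6344 and 6414 genes had a count. The 10 most abundant genes took 20.7% to 52.5% of a library. At these depths a floor of 3 counts per library corresponds to 0.0748 to 0.171 CPM. PCR duplicates cannot be told from independent molecules here, so floors describe counting error only. Genes at 0 in every library numbered 48.

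Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the time point as the group, which left 6327 genes, and libraries were scaled by TMM. A quasi-likelihood model with a mean for each time point was fitted to all 15 libraries together (10 residual degrees of freedom; common biological coefficient of variation 0.418). An F test over the 5 time points and the contrasts 16 h against 0 h, 32 h against 16 h, 48 h against 32 h, 64 h against 48 h, 64 h against 16 h and 64 h against 0 h were computed, with Benjamini-Hochberg adjustment within each and a threshold of 0.05. Samples were grouped by the time point in their titles. The labels name no batch, covariate or control beyond the 0 h samples, and all samples and all columns of the table were used. The words rose and fell are used for genes past the threshold. SE stands for the size of the log2 fold change divided by the square root of its quasi-likelihood F. It was not estimated directly by the model and is approximate.

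Gene lists were fixed before the data were examined, together with the model, the contrasts, the alternatives and the rule for named genes. Of the 33 lists, matched by symbol or description, 2 found no gene. The remaining 31 lists were tested with camera (limma 3.58.1, competitive test with a preset inter-gene correlation of 0.01) in the 6 contrasts, 186 tests adjusted together, of which 54 passed; with the correlation estimated from the data 1 passed. A further 5 lists, for annotations the fixed patterns had missed, were chosen after the data were seen and are named as such where used. The named genes are, per contrast, the 5 largest rises and the 5 largest falls among called and annotated genes with a mean of at least 20 CPM in the higher group and no overlap between the 3 and 3 values, up to 2 called members with the largest change from each list named, a fixed panel of aroma genes (of 12 entries, 6 were found by name), and the 5 most abundant genes of each time point. A gene named outside this rule is marked as singled out after its values were seen.

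The alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios size factors, library size scaling, no low-count filter, a filter of at least 10 CPM on the mean, only the 6 libraries of a comparison, a test against a minimum change of 1.5-fold, the replicate number as a block, list membership by names only, an estimated correlation for camera, and each library left out in turn. A fit without both libraries that stood apart was added after the data were seen. In fits that leave 2 libraries in a group, the spread is pooled over all groups. The pipeline was tested on simulated counts for 6327 genes with the depths and the spread of the 15 libraries, in which genes were changed at 16 h: 6 of 100 genes changed by 2-fold (6%) and 50 of 99 changed by 4-fold (50.5%) were called, with 0 false calls. In the simulated list test the raised list had adjusted p = 1.5e-27 with camera, and 0 of 180 tests of unchanged lists passed. Genes were simulated independently of each other and the lists were random. This therefore cannot show how the list test behaves with correlated genes. Far fewer genes were changed in the simulation than were called in the data (2558 for 16 h against 0 h), which makes the adjusted threshold stricter. The shares of 6% and 50.5% may therefore understate what 3 against 3 libraries resolved in the data.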

Results

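Polyadenylated RNA from whole fermentation broth of the yeast Wickerhamomyces anomalus (organism label Hansenula anomala) was sequenced at 0, 16, 32, 48 and 64 h, with 3 biological replicates per time point. The series concerns the volatile compounds of apricot fermentation. The deposited read counts per gene summed to 17.6 to 40.1 M per library, so that 3 counts in a library, taken as the floor of detection, corresponded to 0.0748 to 0.171 CPM (counts per 1 M counts of the library). Intervals and floors cover counting error only. Gene levels below are CPM scaled by TMM, given as mean ± SD with n = 3 libraries per time point, and adjusted p values come from the edgeR fit of all 15 libraries.

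Transcripts of a pair of glycolytic enzymes had the highest mean shares at 0 h and 16 h, and that of a cell wall protein from 32 h on. Glyceraldehyde-3-phosphate dehydrogenase (WICANDRAFT_25185) took 10.01% ± 0.81 of all counts at 0 h and 11.8% ± 2.55 at 16 h, followed by enolase (WICANDRAFT_30943) with 6.21% ± 0.62 and 7.87% ± 1.01. THI4, a gene of thiamine synthesis, took 5.85% ± 1.96 at 0 h and 6.46% ± 0.72 at 16 h. At 32, 48 and 64 h the highest mean share belonged to CWP2, a cell wall mannoprotein, with 5.34% ± 0.80, 3.39% ± 0.52 and 9.03% ± 3.95. It ranked first in no single 32 h library: CCW12 led in replicates 1 and 2 and the unannotated WICANDRAFT_83923 in replicate 3. At 48 h HSP26 led in replicate 1, WICANDRAFT_83923 in replicate 2 and CWP2 in replicate 3. CWP2 itself did not pass from 16 h to 32 h (log2 fold change -0.40, SE 0.68, adjusted p = 0.686), nor did CCW12 (-0.03, SE 0.62, adjusted p = 0.974); with library size scaling the values were 0.73 and 1.04, and neither passed. Of 6327 genes tested, 4336 (68.5%) changed over the 5 time points. Of these, 1484 (34.2%) had their highest mean level at 0 h, 1009 (23.3%) at 16 h, 496 (11.4%) at 32 h, 515 (11.9%) at 48 h and 832 (19.2%) at 64 h. With library size scaling in place of TMM, the genes highest at 48 h numbered 2638 and those highest at 16 h numbered 165.

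A pair of libraries stood apart from their replicates. Spearman's rho across the 4552 genes with a mean CPM of at least 10 (genes are not independent replicates) was 0.964 between 16 h replicates 1 and 3, but 16 h replicate 2 reached 0.754 at most with either. For 64 h replicate 3 the highest rho with its own group was 0.836, against 0.943 between 64 h replicates 1 and 2, and it reached 0.951 with 32 h replicate 2. For 32 h replicate 3, rho was 0.965 with 48 h replicate 2 and 0.903 with 64 h replicate 1, against 0.886 at most with its own group. Every other library had a rho of at least 0.886 with a library of its own group. Libraries of 32 h and 48 h correlated with each other at up to 0.965. For 48 h replicate 1, rho was 0.954 with 32 h replicate 2, against 0.934 at most with its own group. For 48 h replicate 2, rho with its own group was 0.954 at most, under its 0.965 with 32 h replicate 3. Both libraries that stood apart were kept in all results below, and counts without them are given where they bear on a result.

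**Figure D1:**
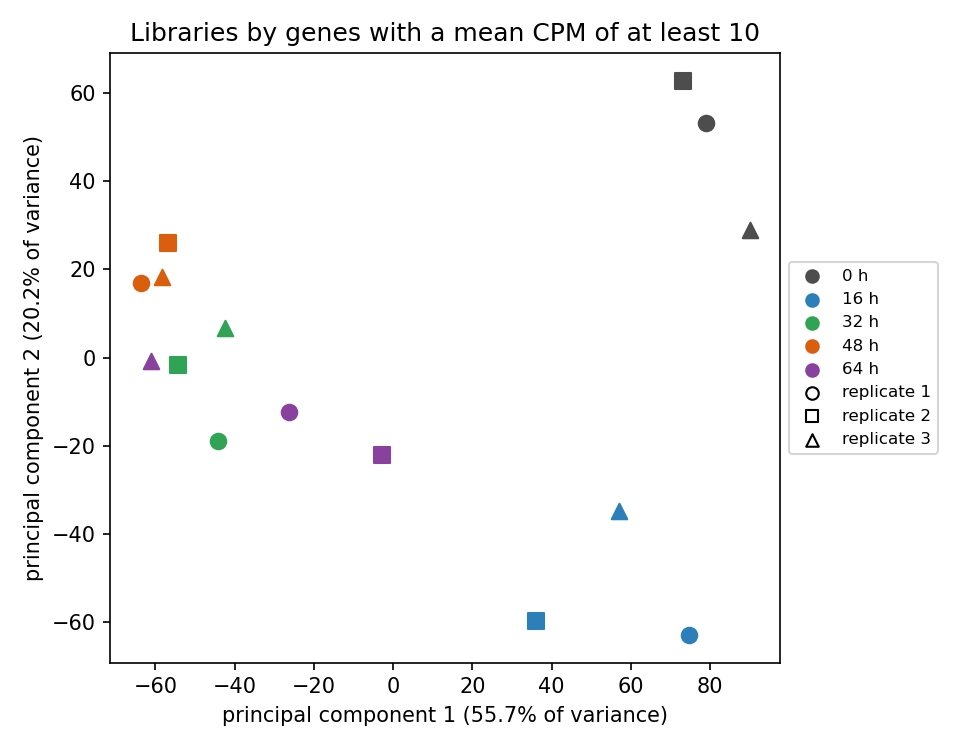
Principal components 1 and 2 of log2(CPM + 1) of the 4552 genes with a mean CPM of at least 10, with 1 point per library, colours for the time points and symbols for the replicates; the axes carry 55.7% and 20.2% of the variance. All 0 h and 16 h libraries have positive scores on component 1 (36.1 to 90.1), all later libraries have negative ones (-2.74 to -63.7), and 64 h replicate 3 (-61.1) sits among the 32 h and 48 h libraries.

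Between 0 h and 16 h, the largest rise by the rule for named genes (annotated, no overlap of the 3 and 3 values) was that of ADH3 (WICANDRAFT_36130), an alcohol dehydrogenase gene, from 14.1 ± 4.8 to 33500 ± 17500 CPM (log2 fold change 11.22, SE 0.95, adjusted p = 2.19e-06). Both ISP4-family genes among the largest rises, a family that includes oligopeptide transporters, rose as well: WICANDRAFT_33562 went from 12.6 ± 1.11 to 7520 ± 267 CPM (595-fold) and WICANDRAFT_57692 from 10.4 ± 0.391 to 2250 ± 384 CPM (217-fold). A sorbitol dehydrogenase gene (WICANDRAFT_36899) rose 249-fold and an aspartyl protease gene (WICANDRAFT_14182) 151-fold. The largest fall by this rule was that of ADH4 (WICANDRAFT_80232), a class IV alcohol dehydrogenase gene, from 9790 ± 1810 to 28.1 ± 15.6 CPM (log2 fold change -8.44, SE 0.81, adjusted p = 6.18e-06). A gene of the SOR/SNZ family, known for vitamin B6 synthesis, fell from 3750 ± 1160 to 14.5 ± 8.15 CPM (WICANDRAFT_30969, 259-fold lower). The zinc transporter gene ZRT1 fell from 7250 ± 2630 to 31.6 ± 6.81 CPM (230-fold lower). A related Fe/Zn transporter gene (WICANDRAFT_85399) was 81.8-fold lower at 16 h, and WICANDRAFT_35981, annotated as a cobalamin synthesis protein, 75.1-fold lower. Without 16 h replicate 2 the log2 fold change of WICANDRAFT_85399 moved from -6.35 to -7.05. In total 1432 genes rose and 1126 fell (40.4% of those tested), 1324 and 1026 of them by at least 2-fold. Risen genes made up 56% of the calls with TMM and 26.1% (620 rose, 1753 fell) with library size scaling, which shifted the median of all genes by -0.69 on the log2 scale.

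Most genes for cytosolic ribosomal proteins and of DNA replication were lower at 16 h than at 0 h. Of 96 genes for cytosolic ribosomal proteins, 79 fell, 0 rose and 17 did not pass (87 fell adjusted over the list alone), with a median log2 fold change of -2.44. RPL39 fell from 213 ± 116 to 6.62 ± 3.50 CPM and RPS17B from 634 ± 467 to 36.1 ± 13.4 CPM. The list passed the camera set test at adjusted p = 3.77e-22, and had adjusted p = 0.486 with an estimated correlation. These genes are short (median 738 bp, against 1215 bp for all tested genes), and the 0 h libraries differed from each other by gene length: the rank correlation across 6327 genes of each library's log2 ratio to its group mates with length was 0.418, 0.418 and -0.478. Replicates 1 and 2 were alike (rho 0.988), so these values set replicate 3 apart. The log2 fold changes of 16 h against 0 h had a rank correlation of -0.028 with length across the 6327 genes. Of 43 genes of DNA replication and histones, 35 fell and 0 rose (35 adjusted over the list alone; median -2.35). Examples were HHF2, histone H4, from 2390 ± 1130 to 109 ± 43.4 CPM, and POL30, the sliding clamp of DNA polymerases, from 53 ± 41.3 to 2.16 ± 1.20 CPM. Without 0 h replicate 3 the log2 fold change moved from -4.60 to -3.74 for POL30 and from -4.13 to -3.33 for RPS17B. The DNA replication and histone list was the only list to pass in any comparison with the preset (adjusted p = 1.89e-15) and with an estimated correlation (adjusted p = 0.0321).

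Most genes of 2 amino acid synthesis lists fell over the same interval. Of 29 genes of arginine, lysine and histidine synthesis, 21 fell and 2 rose (21 and 2 adjusted over the list alone; median -1.63), with an acetylornithine aminotransferase gene (WICANDRAFT_61589) 15.2-fold lower. In sulfate assimilation and methionine and cysteine synthesis, 16 of 21 genes fell and 1 rose (17 and 1 adjusted over the list alone; median -1.90). MET3, ATP sulfurylase, fell from 300 ± 31.6 to 6.93 ± 2.20 CPM, and MET14, adenylylsulfate kinase, from 145 ± 55.3 to 3.18 ± 0.459 CPM. Both lists passed camera (adjusted p = 1.8e-08 and 6.49e-08) and had adjusted p = 0.253 with an estimated correlation. The other amino acid synthesis lists did not pass. Of 8 branched-chain genes 1 fell and 0 rose (0 adjusted over the list alone; camera adjusted p = 0.411). The call of that gene, ILV6, ended without 0 h replicate 3, 16 h replicates 1 or 2, 32 h replicates 1 or 2, or any 48 h library, and with the replicate block. Of 12 aromatic genes 4 fell and 2 rose (4 and 3 adjusted over the list alone; camera adjusted p = 0.36).

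From 0 h to 16 h most genes of fatty acid breakdown rose, and in the alcohol dehydrogenase and autophagy lists more genes rose than fell. Of 30 genes of beta-oxidation and the peroxisome, 21 rose and 0 fell (21 adjusted over the list alone; median 1.81). The thiolase gene POT1 went from 8.28 ± 4.14 to 144 ± 92.2 CPM and the catalase gene CTA1 from 14.6 ± 2.64 to 220 ± 82.1 CPM. Without 16 h replicate 2 the log2 fold change of POT1 moved from 4.12 to 3.49. Camera gave adjusted p = 3.75e-07, and adjusted p = 0.347 with an estimated correlation. Of 20 genes listed as alcohol dehydrogenases, which include short-chain dehydrogenases and the regulator CCR4, 12 rose and 3 fell (13 and 3 adjusted over the list alone; median 1.36; camera adjusted p = 0.00383, and adjusted p = 0.253 with an estimated correlation). ADH3 and ADH4 were the members with the largest changes, in opposite directions. Of 24 genes of autophagy and vacuolar proteases, 9 rose and 0 fell (9 adjusted over the list alone), with APE1, a vacuolar aminopeptidase, 9.63-fold higher and a vacuolar protease B gene (WICANDRAFT_64521) 4.56-fold higher (camera adjusted p = 0.0294, and adjusted p = 0.253 with an estimated correlation). Without both libraries that stood apart, 13 genes of this list rose.

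**Figure D2:**
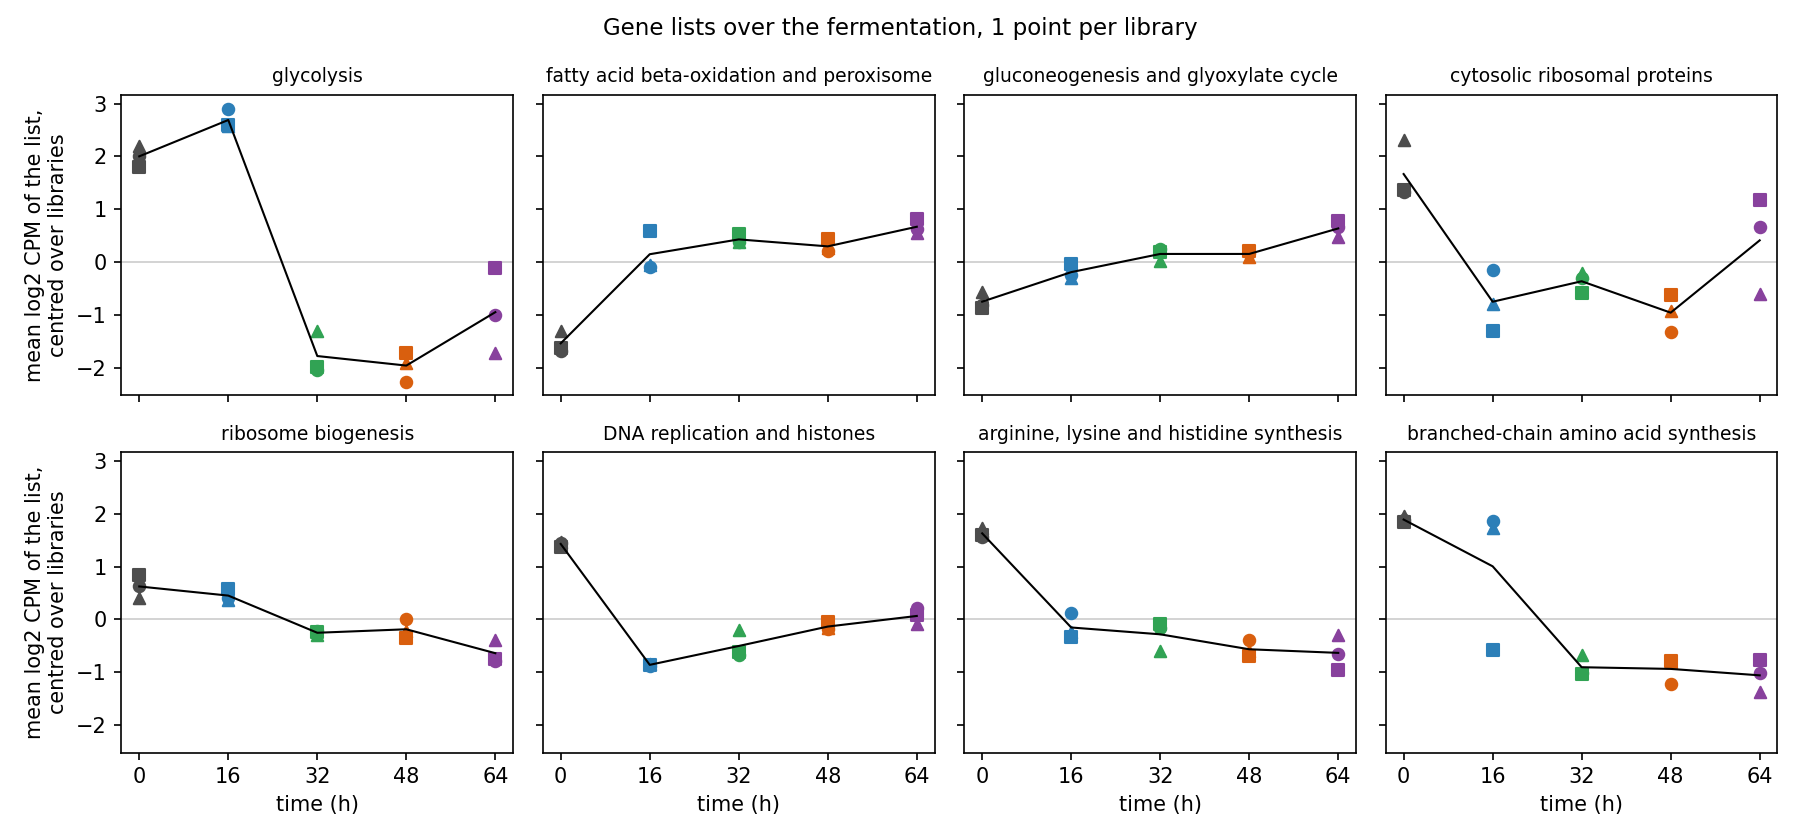
Mean log2 CPM of the tested members of 8 gene lists in each library, centred over the 15 libraries, against time in hours; points are libraries, symbols replicates, and the black line joins the means of the 3 replicates. Glycolysis genes lie at 1.79 to 2.91 in the 0 h and 16 h libraries and at -0.121 or lower in all later ones, and ribosomal protein genes lie at 1.33 to 2.30 at 0 h and at -0.159 or lower at 16, 32 and 48 h; with library size scaling the list medians for ribosome biogenesis from 16 h to 32 h have the opposite sign.

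Between 16 h and 32 h, several transcripts of sugar breakdown fell. Invertase (WICANDRAFT_35787), which splits sucrose, went from 1060 ± 881 to 1.22 ± 0.531 CPM (log2 fold change -9.75, SE 1.10, adjusted p = 4.27e-05). Its level was 62 CPM in 16 h replicate 2 and at least 1360 CPM in the other 16 h libraries. A class V alcohol dehydrogenase gene (WICANDRAFT_62195) fell from 40600 ± 24100 to 136 ± 67.4 CPM (300-fold lower), and a transporter gene of the major facilitator superfamily (WICANDRAFT_84441) from 80100 ± 25700 to 294 ± 141 CPM (272-fold lower). Hexokinase gene WICANDRAFT_65261 was 240-fold lower at 32 h and WICANDRAFT_77374, a predicted haloacid-halidohydrolase family gene, 215-fold lower. The largest rise by the rule for named genes was that of PCK1, which encodes phosphoenolpyruvate carboxykinase, a key enzyme of gluconeogenesis, from 24.2 ± 26.2 to 821 ± 480 CPM (log2 fold change 5.08, SE 0.89, adjusted p = 0.000872). Aldehyde dehydrogenase gene WICANDRAFT_25445 rose 26.2-fold, the predicted membrane protein gene WICANDRAFT_38748 22.3-fold, the methyltransferase gene WICANDRAFT_86031 16.4-fold and the cyclin B gene WICANDRAFT_31360 16.1-fold. Without 16 h replicate 2 the log2 fold change moved to 6.50 for PCK1 and from 4.03 to 5.14 for WICANDRAFT_86031, and without 32 h replicate 3 it moved from -7.75 to -8.38 for WICANDRAFT_77374. In total 889 genes rose and 1118 fell (31.7% of those tested), 807 and 1038 of them by at least 2-fold.

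These counts rested on individual libraries and on the scaling. Risen genes numbered 558 without 16 h replicate 3 and 590 without 32 h replicate 2, and fallen genes 671 without 32 h replicate 1 and 689 without 32 h replicate 2. Without both libraries that stood apart, 1445 genes rose and 1526 fell. Library size scaling shifted the median of all genes by 1.16 on the log2 scale and gave 2809 risen and 285 fallen genes (90.8% risen, against 44.3% with TMM).

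Of the 20 genes listed under glycolysis, 16 fell from 16 h to 32 h, 0 rose and 4 did not pass (16 fell adjusted over the list alone), with a median log2 fold change of -4.73. The median was -3.49 with library size scaling, where 16 fell and 1 rose. Enolase (WICANDRAFT_30943) went from 152000 ± 61000 to 873 ± 836 CPM (174-fold lower) and PGK1, phosphoglycerate kinase, from 68700 ± 32400 to 760 ± 402 CPM (90.3-fold lower). The list holds members outside the pathway, such as UTR4, an enolase-phosphatase. Camera gave adjusted p = 2.63e-16, and adjusted p = 0.237 with an estimated correlation. Glyceraldehyde-3-phosphate dehydrogenase gene WICANDRAFT_25185 and WICANDRAFT_46076, annotated with pyruvate decarboxylase activity, fell from 232000 ± 113000 to 4330 ± 2930 CPM and from 40700 ± 23800 to 390 ± 222 CPM; the latter entered through a list chosen after the data were seen. Without 32 h replicate 3 the log2 fold change moved from -7.45 to -8.61 for enolase and from -5.74 to -6.46 for WICANDRAFT_25185. THI4 was 39.2-fold lower at 32 h. ADH3 did not pass (log2 fold change 0.03, SE 0.62, adjusted p = 0.972) and stood at 34300 ± 11300 CPM at 32 h.

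Part of the genes of ribosome biogenesis, of trehalose, glycogen and glycerol metabolism and of branched-chain amino acid synthesis were lower at 32 h than at 16 h, though the medians of the former 2 lists had the opposite sign with library size scaling. Of 93 ribosome biogenesis genes, 29 fell and 1 rose (29 and 1 adjusted over the list alone; median -0.72, and 0.41 with library size scaling), with the RNA helicase gene DBP2 8.94-fold lower and UTP13, a subunit of the complex that processes 18S rRNA, 6.37-fold lower. Camera gave adjusted p = 1.27e-05, and adjusted p = 0.486 with an estimated correlation. Of 22 genes of trehalose, glycogen and glycerol metabolism, 11 fell and 0 rose (12 adjusted over the list alone; median -0.98, and 0.18 with library size scaling). A glycerol-3-phosphate dehydrogenase gene (WICANDRAFT_30049) was 109-fold lower and GPH1, glycogen phosphorylase, 22.7-fold lower (camera adjusted p = 0.000328, and adjusted p = 0.447 with an estimated correlation). Without 32 h replicate 1, 7 genes of this list fell. Of 8 genes of branched-chain amino acid synthesis, 5 fell and 0 rose (6 adjusted over the list alone; median -2.32; camera adjusted p = 0.00605, and adjusted p = 0.486 with an estimated correlation). LEU1 fell from 278 ± 240 to 17.6 ± 1.71 CPM and ILV5 from 978 ± 867 to 47.3 ± 45.8 CPM, and 7 of the 8 genes fell without both libraries that stood apart. The log2 fold change of LEU1 moved from -3.98 to -3.26 without 16 h replicate 3, and that of ILV5 from -4.37 to -3.63 without 16 h replicate 1 and to -5.55 without 32 h replicate 3.

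**Figure D3:**
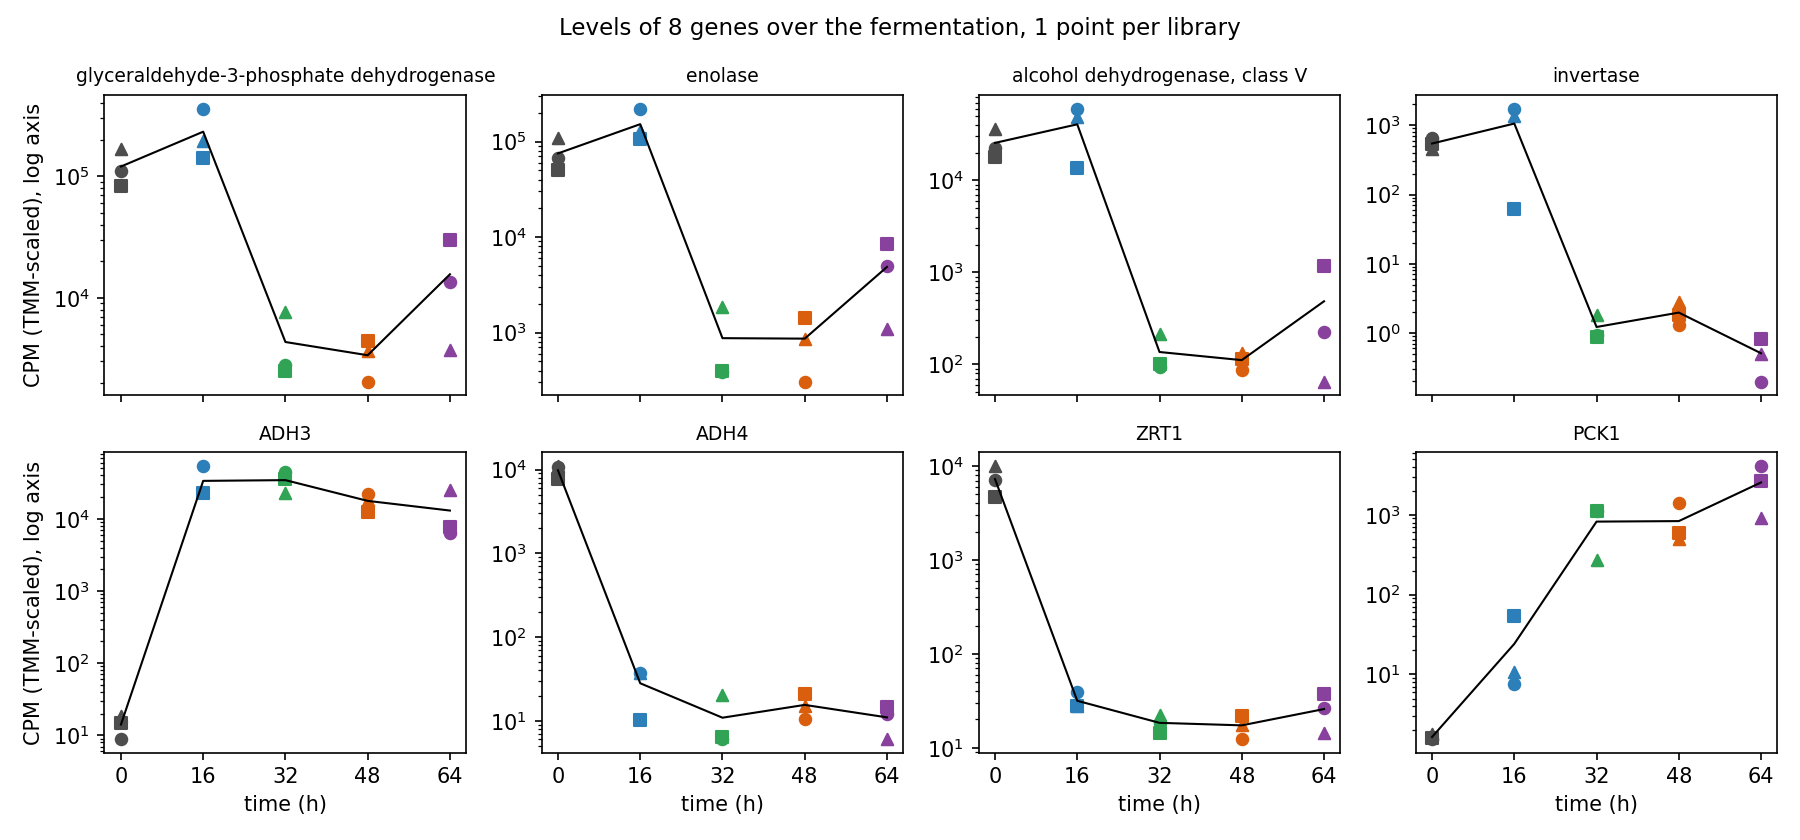
TMM-scaled CPM of 8 genes on a log axis against time in hours; points are libraries, symbols replicates, and the black line joins the means of the 3 replicates. Enolase lies at 50900 CPM or higher in the 0 h and 16 h libraries and at 8540 CPM or lower in all later ones, ADH3 rises from at most 18.4 CPM at 0 h to at least 22800 CPM at 16 h, and PCK1 lies at 1.81 CPM or lower at 0 h and at 919 CPM or higher at 64 h.

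From 16 h to 32 h further lists had more risen than fallen members, though fewer than 1 in 2 members rose. Of 43 genes of DNA replication and histones, 17 rose and 6 fell (17 and 6 adjusted over the list alone; median 0.46; camera adjusted p = 0.0423, and adjusted p = 0.482 with an estimated correlation). The members with the largest changes went the other way: HTB2, histone H2B, fell from 250 ± 202 to 7.45 ± 2.18 CPM and HTA2, histone H2A, from 192 ± 85.6 to 10.8 ± 0.553 CPM. The log2 fold change of HTB2 moved from -5.07 to -4.21 without 16 h replicate 1. Of 71 heat shock protein and chaperone genes, 20 rose and 5 fell (25 and 5 adjusted over the list alone; median 0.58), with HSP82 14.2-fold higher and an HSP110-family gene (WICANDRAFT_75947) 18.1-fold lower (log2 fold change -4.18, and -5.22 without 32 h replicate 3). Camera gave adjusted p = 0.0128, and adjusted p = 0.599 with an estimated correlation. Risen members numbered 10 without 16 h replicate 1, 8 without 16 h replicate 3, 8 without 32 h replicate 1 and 9 without 32 h replicate 2, and fallen members 3 without any of these, or without 48 h replicate 1, 2 or 3; without both libraries that stood apart, 32 rose and 8 fell. Of 21 sulfur amino acid genes, 6 rose and 2 fell (7 and 3 adjusted over the list alone; median 1.23; camera adjusted p = 0.0448, and adjusted p = 0.593 with an estimated correlation), with MET5, sulfite reductase, 10.4-fold higher and the regulator MET4 7.71-fold higher.

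From 32 h to 48 h, edgeR called 0 genes risen and 0 fallen at the adjusted threshold; 347 genes had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 8 fallen genes. The most abundant transcripts differed by less than the test could resolve: CCW12, a cell wall protein, stood at 43700 ± 25800 and 18400 ± 4700 CPM (log2 fold change -1.25, SE 0.63, adjusted p = 0.783) and CWP2 at 44600 ± 15100 and 20100 ± 3430 CPM (-1.15, SE 0.68, adjusted p = 0.783). No gene list had a called member. Cytosolic ribosomal proteins had a median log2 fold change of -0.62 with 0 of 96 genes called (0 adjusted over the list alone; camera adjusted p = 2.38e-14, and adjusted p = 0.589 with an estimated correlation). Across 6327 genes, log2 fold changes of this comparison had a rank correlation of 0.217 with gene length, against at most 0.065 in size in the other comparisons.

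From 48 h to 64 h, 1 gene fell and 0 rose at the adjusted threshold of edgeR, and 1559 genes had an unadjusted p under 0.05. The fallen gene, WICANDRAFT_60153, has no annotation and was singled out after its values were seen; it went from 49.3 ± 12.3 to 10.3 ± 4.65 CPM (log2 fold change -2.26, SE 0.34, adjusted p = 0.0432). With 1 library left out, this call held only without 0 h replicate 3, 16 h replicate 2 or 64 h replicate 3, and it ended with the replicate block. The number of calls depended on 64 h replicate 3. Without it, 629 genes rose and 529 fell; without 16 h replicate 2, 483 and 378; without 0 h replicate 3, 182 and 68. Without both libraries that stood apart, 927 rose and 998 fell. DESeq2 called 589 risen and 287 fallen genes with all libraries, and limma-voom 19 and 17. Genes for cytosolic ribosomal proteins had a median log2 fold change of 1.66, with 0 of 96 called over all genes but 78 risen and 2 fallen adjusted over the list alone (camera adjusted p = 1.41e-27, and adjusted p = 0.482 with an estimated correlation); 84 rose and 2 fell without both libraries that stood apart. Glycolysis genes had a median of 1.15, with 0 of 20 called and 5 risen adjusted over the list alone (camera adjusted p = 0.000138, and adjusted p = 0.482 with an estimated correlation).

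At 64 h against 16 h, genes of gluconeogenesis and the glyoxylate cycle were among the largest rises. PCK1 went from 24.2 ± 26.2 to 2540 ± 1580 CPM (log2 fold change 6.71, SE 0.96, adjusted p = 0.000144; 8.12 without 16 h replicate 2 and 8.52 without both libraries that stood apart) and MLS1, malate synthase, from 28.3 ± 7.36 to 892 ± 398 CPM (31.5-fold). A reductase gene (WICANDRAFT_88497) rose 57.7-fold, the aldehyde dehydrogenase gene WICANDRAFT_25445 57.2-fold and a permease gene of the major facilitator superfamily (WICANDRAFT_84684) 41.7-fold. WICANDRAFT_78559, annotated as a homeobox transcription factor, fell from 525 ± 40.3 to 3.53 ± 2.44 CPM (log2 fold change -7.21, SE 0.55, adjusted p = 3.41e-06). WICANDRAFT_77374 was 210-fold lower, hexokinase gene WICANDRAFT_65261 144-fold lower and transporter gene WICANDRAFT_63188 116-fold lower. Without 64 h replicate 2 the log2 fold changes of these 4 genes moved from -7.21 to -7.91, from -7.71 to -8.98, from -7.17 to -9.60 and from -6.86 to -8.48. Invertase (WICANDRAFT_35787) fell to 0.509 ± 0.313 CPM, close to the floor of 3 counts, so no fold is given. In total 1138 genes rose and 1314 fell (38.8% of those tested), 1050 and 1217 by at least 2-fold, and 1447 and 1599 without both libraries that stood apart. Risen genes made up 46.4% of the calls with TMM and 85.6% (2303 rose, 386 fell) with library size scaling, which shifted the median of all genes by 0.93 on the log2 scale.

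The groups lower at 64 h than at 16 h included glycolysis, with 16 of 20 genes fallen and 0 risen (16 adjusted over the list alone; median -3.67; camera adjusted p = 3.01e-10, and adjusted p = 0.253 with an estimated correlation). A predicted phosphoglycerate mutase gene (WICANDRAFT_25393) was 45.2-fold lower (log2 fold change -5.50, and -4.81 without 16 h replicate 2). Of 93 ribosome biogenesis genes, 55 fell and 0 rose (59 adjusted over the list alone; median -1.13), with UTP13 9.79-fold lower (camera adjusted p = 6.05e-10, and adjusted p = 0.359 with an estimated correlation). In branched-chain amino acid synthesis 7 of 8 genes fell and 0 rose (7 adjusted over the list alone), with LEU1 23.4-fold lower (log2 fold change -4.55, and -3.83 without 16 h replicate 3); 4 fell without 64 h replicate 1 (camera adjusted p = 0.00453, and adjusted p = 0.486 with an estimated correlation). Trehalose, glycogen and glycerol genes numbered 8 fallen and 1 risen of 22 (8 and 1 adjusted over the list alone; median -0.66, and 0.22 with library size scaling; camera adjusted p = 0.00555, and adjusted p = 0.486 with an estimated correlation). Genes for cytosolic ribosomal proteins numbered 49 risen and 2 fallen of 96 (55 and 2 adjusted over the list alone; median 1.27), with RPL21A from 21.9 ± 5.59 to 278 ± 117 CPM (camera adjusted p = 9.85e-08, and adjusted p = 0.708 with an estimated correlation). This count was 22 without 16 h replicate 3, 29 without 64 h replicate 1 and 20 without 64 h replicate 2, and 61 without both libraries that stood apart. DNA replication and histone genes numbered 21 risen and 5 fallen of 43 (23 and 5 adjusted over the list alone; median 1.18; camera adjusted p = 6.45e-05, and adjusted p = 0.253 with an estimated correlation), with HTA2 12-fold lower.

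Over the whole course, from 0 h to 64 h, genes of gluconeogenesis and the glyoxylate cycle were among the largest rises. PCK1 went from 1.65 ± 0.138 to 2540 ± 1580 CPM (log2 fold change 10.58, SE 1.13, adjusted p = 5.84e-06) and ICL1, isocitrate lyase of the glyoxylate cycle, from 3.68 ± 3.37 to 3270 ± 1610 CPM (893-fold). The ISP4-family gene WICANDRAFT_33562 rose 1050-fold and ADH3 928-fold (log2 fold change 9.86, and 8.96 without 64 h replicate 3). The log2 fold change of ICL1 moved from 9.80 to 10.88 without 0 h replicate 3. HSP26, a small heat shock protein gene, went from 11.2 ± 3.22 to 11500 ± 16400 CPM (log2 fold change 10, and 7.49 without 64 h replicate 3). ADH4 fell from 9790 ± 1810 to 11 ± 4.43 CPM (log2 fold change -9.80, SE 0.86, adjusted p = 1.21e-06), WICANDRAFT_77374 379-fold (log2 fold change -8.57, and -9.83 without 64 h replicate 2) and the glycerol-3-phosphate dehydrogenase gene WICANDRAFT_30049 328-fold. Invertase fell from 545 ± 97 to 0.509 ± 0.313 CPM. A permease gene, WICANDRAFT_24632, stood at 25 ± 2.89 CPM at 0 h and at a mean of 0.0456 CPM, under the floor, at 64 h. In total 1680 genes rose and 1632 fell (52.3% of those tested), 1553 and 1479 by at least 2-fold. Risen genes made up 50.7% of the calls with TMM and 61.2% (1720 rose, 1091 fell) with library size scaling, which shifted the median of all genes by 0.26 on the log2 scale.

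Of 35 genes of gluconeogenesis and the glyoxylate cycle, 16 rose and 3 fell from 0 h to 64 h (16 and 3 adjusted over the list alone; median 0.52; camera adjusted p = 0.0218, and adjusted p = 0.359 with an estimated correlation). Of 30 genes of beta-oxidation and the peroxisome, 22 rose and 1 fell (23 and 1 adjusted over the list alone; median 2.08; camera adjusted p = 7.07e-08, and adjusted p = 0.253 with an estimated correlation). An enoyl-CoA isomerase gene (WICANDRAFT_70060) went from 0.385 ± 0.230 to 65.6 ± 6.34 CPM and PEX11, a peroxisome biogenesis gene, from 4.20 ± 1.07 to 217 ± 58.2 CPM. Autophagy and vacuolar protease genes numbered 11 risen and 1 fallen of 24 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0283, and adjusted p = 0.253 with an estimated correlation), with ATG18 5.81-fold higher. Glycolysis genes numbered 15 fallen and 0 risen of 20 (15 and 1 adjusted over the list alone; median -3.26; camera adjusted p = 2.7e-05, and adjusted p = 0.389 with an estimated correlation), with PFK1, phosphofructokinase, 49.3-fold lower (log2 fold change -5.62, and -6.52 without 64 h replicate 2).

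Most genes of several amino acid synthesis lists and of ribosome biogenesis were lower at 64 h than at 0 h. Arginine, lysine and histidine synthesis had 23 of 29 genes fallen and 2 risen (23 and 2 adjusted over the list alone; median -2.32; camera adjusted p = 1.01e-08, and adjusted p = 0.253 with an estimated correlation), with HIS5 36.1-fold lower. All 8 branched-chain amino acid synthesis genes had fallen adjusted over the list alone and 7 over all genes (median -2.63; camera adjusted p = 0.00221, and adjusted p = 0.482 with an estimated correlation), with LEU1 28.7-fold lower and ILV2, acetolactate synthase, 21.9-fold lower. Sulfur amino acid genes numbered 14 fallen and 2 risen of 21 (15 and 2 adjusted over the list alone; camera adjusted p = 0.000741, and adjusted p = 0.414 with an estimated correlation), with MET6, methionine synthase, 19.1-fold lower. Aromatic amino acid synthesis genes numbered 7 fallen and 0 risen of 12 (7 adjusted over the list alone; camera adjusted p = 0.0283, and adjusted p = 0.359 with an estimated correlation), with ARO4 13.9-fold lower. Ribosome biogenesis had 56 of 93 genes fallen and 1 risen (61 and 1 adjusted over the list alone; median -1.16; camera adjusted p = 1.15e-08, and adjusted p = 0.447 with an estimated correlation). Of 96 genes for cytosolic ribosomal proteins, which the differences by gene length among the 0 h libraries also touch, 48 fell and 3 rose (50 and 3 adjusted over the list alone; median -1.20; camera adjusted p = 0.000184, and adjusted p = 0.771 with an estimated correlation). The 3 risen genes became 1 without 0 h replicate 1, 0 h replicate 2 or 64 h replicate 2, 9 without 0 h replicate 3 and 6 without 64 h replicate 3. DNA replication and histone genes numbered 20 fallen and 4 risen of 43 (21 and 4 adjusted over the list alone; camera adjusted p = 0.00314, and adjusted p = 0.359 with an estimated correlation), with HTA2 189-fold lower and HTB2 from 3750 ± 2370 to 25.2 ± 16.1 CPM. Without 0 h replicate 3 their log2 fold changes moved from -7.56 to -6.88 and from -7.22 to -6.57.

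Among the routes to aroma compounds, genes changed in the Ehrlich pathway, which turns amino acids into higher alcohols. The transaminase gene ARO9 rose from 3.37 ± 1.01 CPM at 0 h to 66.4 ± 60.2 at 16 h (log2 fold change 4.29, SE 0.72, adjusted p = 0.000344; 3.38 without 16 h replicate 3) and stood at 186 ± 26.5 CPM at 64 h (54.8-fold above 0 h). ARO8, its paralog in baker's yeast, rose from 88.1 ± 21.8 to 483 ± 273 CPM between 16 h and 32 h (log2 fold change 2.45, SE 0.54, adjusted p = 0.00395). The decarboxylase gene ARO10 was 3.51-fold higher at 64 h than at 0 h (log2 fold change 1.81, adjusted p = 0.00221), and the branched-chain transaminase gene BAT1 5.04-fold lower (log2 fold change -2.33, adjusted p = 0.00203). Without 64 h replicate 3 these values moved to 1.15 and -3.30. Of the 7 genes of the Ehrlich list, 2 rose from 0 h to 16 h, 3 rose from 16 h to 32 h and 3 rose and 1 fell from 0 h to 64 h. The list did not pass camera in any of these comparisons (adjusted p = 0.584, 0.199 and 0.432). Risen members from 16 h to 32 h numbered 1 without 16 h replicate 3.

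No gene matched the names or descriptions fixed for ester synthesis. The esterase gene IAH1, which hydrolyses isoamyl acetate in baker's yeast, stood at 16.7 ± 7.30, 12.3 ± 2.81, 16.5 ± 4.50, 13.1 ± 1.13 and 15.8 ± 4.09 CPM at 0, 16, 32, 48 and 64 h, and passed in none of the 6 comparisons with TMM (adjusted p from 0.313 to 0.848). With library size scaling it was called higher at 32 h than at 16 h (log2 fold change 1.60, against 0.43 with TMM; adjusted p = 0.00929) and at 64 h than at 16 h (1.29 against 0.36; adjusted p = 0.0309). Of 19 genes of ester hydrolysis, 6 rose and 0 fell from 0 h to 16 h, among them a carbohydrate esterase gene (WICANDRAFT_14088, 9.56-fold; log2 fold change 3.26, and 2.12 without 16 h replicate 2) and the lipase gene TGL3 (2.88-fold; not called with library size scaling, log2 fold change 0.85 against 1.52). From 16 h to 32 h 1 rose and 3 fell, with a triglyceride lipase gene (WICANDRAFT_22393) 5.18-fold lower (not called with library size scaling), and 1 fell without 32 h replicate 1 or 32 h replicate 2. From 16 h to 64 h 1 rose and 2 fell (1 to 3 and 2 to 5 with 1 library left out). From 0 h to 64 h 6 rose and 3 fell, and 0 fell without 0 h replicate 1 and 1 without 0 h replicate 2 or 64 h replicate 1. Camera gave adjusted p = 0.21, 0.765, 0.667 and 0.523 for these comparisons. The counts adjusted over the list alone were the same. The acetyl-CoA synthetase gene ACS2 fell from 376 ± 265 CPM at 16 h to 98 ± 40.6 at 32 h (log2 fold change -1.94, SE 0.71, adjusted p = 0.0485), and with 1 library left out this call held only without 16 h replicate 2 or 64 h replicate 3. It also ended with library size scaling (-0.62, adjusted p = 0.426), limma-voom (-1.54, adjusted p = 0.12) and the replicate block (-1.89, adjusted p = 0.0886). ACS1 stood at 265 ± 71.2, 101 ± 23.2, 58.3 ± 2.69, 57.3 ± 4.44 and 293 ± 289 CPM at 0, 16, 32, 48 and 64 h. It rose from 16 h to 64 h (log2 fold change 1.54, SE 0.55, adjusted p = 0.0387), a call that ended without 0 h replicate 1, any 16 h library or 64 h replicate 2 (0.38 without the last), with limma-voom (1.03, adjusted p = 0.141) and with the replicate block (1.41, adjusted p = 0.0946). It did not pass from 0 h to 64 h (0.14, SE 0.54, adjusted p = 0.838). In a list of 5 genes chosen after the data were seen, whose annotation names alcohol acyltransferase activity, 2 rose and 2 fell from 0 h to 16 h, 0 and 1 from 16 h to 32 h and from 16 h to 64 h, and 1 and 1 from 0 h to 64 h (0 to 2 fallen with 1 library left out). The counts adjusted over the list alone were the same. WICANDRAFT_63216 rose from 34.7 ± 7.29 to 613 ± 290 CPM (log2 fold change 4.14, SE 0.46, adjusted p = 1.62e-05) and fell to 58.6 ± 11.5 CPM at 32 h (-3.39, SE 0.44, adjusted p = 0.000111). The fallen genes were WICANDRAFT_63213 (-1.01, SE 0.36, adjusted p = 0.0374) and WICANDRAFT_30278 (-1.07, SE 0.41, adjusted p = 0.0472). The former call ended without any 0 h library, 16 h replicates 1 or 2, 32 h replicate 1 or 48 h replicates 1 or 3, and the latter without 0 h replicates 1 or 2, 16 h replicates 1 or 3, or replicates 1 or 2 of 32, 48 or 64 h. The latter also ended with limma-voom and with the replicate block. A further list chosen after the data were seen held 4 predicted alpha/beta hydrolase genes. From 16 h to 32 h WICANDRAFT_48865 rose (log2 fold change 1.37, adjusted p = 0.0158) and WICANDRAFT_76171 fell (-1.56, adjusted p = 0.016). WICANDRAFT_27004 (1.37, adjusted p = 0.132) and WICANDRAFT_32991 (-0.48, adjusted p = 0.356) did not pass. Without both libraries that stood apart WICANDRAFT_27004 rose too (1.46, adjusted p = 0.0201). These 4 genes are outside the 141 combinations below.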

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

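The fit without both libraries that stood apart (16 h replicate 2 and 64 h replicate 3) was chosen after the data were seen; the other alternatives were planned. Among 141 combinations of a named gene and a comparison, under the alternatives that refit all genes, every call past the threshold kept its direction; 96 calls stayed past the threshold under every planned one, and 12 did not. Limma-voom ended 4 of these calls, library size scaling 4, and the replicate block 6; for 1 (WICANDRAFT_84441, 32 h against 16 h) DESeq2 gave no adjusted p, with a log2 fold change of -8.10 against -8.09; and leaving out 1 library ended between 1 and 8 and moved the fold of 35 by more than 1.5 times. Among pairs without a call, library size scaling gave 5 calls, DESeq2 3, and leaving out 64 h replicate 3 gave 6.

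The counts of changed genes moved more. Library size scaling gave 620 risen and 1753 fallen genes for 16 h against 0 h (TMM: 1432 and 1126), 2809 and 285 for 32 h against 16 h (889 and 1118), 15 and 181 for 64 h against 48 h (0 and 1) and 2303 and 386 for 64 h against 16 h (1138 and 1314). These shifts follow from the scaling itself, since it moved the median of all genes by -0.69, 1.16, -0.68 and 0.93 on the log2 scale. With only the 6 libraries compared, 537 rose and 690 fell for 32 h against 16 h, 561 and 576 for 64 h against 16 h, and 0 fell for 64 h against 48 h, with fewer samples behind the spread. A minimum change of 1.5-fold gave 511 and 738 for 32 h against 16 h and 0 fallen genes for 64 h against 48 h.

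For 64 h against 48 h, median-of-ratios size factors gave 124 risen and 39 fallen genes, a mean CPM of at least 10 gave 113 and 58, DESeq2 589 and 287, and limma-voom 19 and 17; the cause was not tested. DESeq2 gave 8 fallen genes for 48 h against 32 h. Without both libraries that stood apart, 927 genes rose and 998 fell for 64 h against 48 h and 1445 rose for 32 h against 16 h.

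With each library left out in turn, the genes changed over time numbered 3706 to 4810. For 32 h against 16 h between 558 (without 16 h replicate 3) and 1238 (without 16 h replicate 2) rose and between 671 (without 32 h replicate 1) and 1344 (without 16 h replicate 2) fell, and for 64 h against 48 h between 0 and 629 rose and between 0 and 529 fell, the highest without 64 h replicate 3. The counts of the other comparisons stayed within 1.5 times those with all libraries. The replicate number as a block gave 0 fallen genes for 64 h against 48 h. Pairing of samples by number across time points was not evident. Of 30 correlations of residuals between libraries that share a number, 7 were above 0.1 (range -0.697 to 0.572). In 3 of the 30 the library with the same number gave the highest correlation. With 3 libraries per group this cannot exclude repeated sampling of a culture, since the labels do not say what a number marks.

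Of the list tests, 54 of 186 passed with the preset correlation and 1 with an estimated correlation. With the preset, 22 of 100 groupings of the libraries, the real one included, passed as many. The number that passed with the preset therefore does not by itself show differences between time points. Between 46 and 58 passed with the preset and 1 library left out. Depth limits genes near the floor of 0.0748 to 0.171 CPM. In simulated counts with the real depths and spread together, 6% of 2-fold and 50.5% of 4-fold changes were called. Far fewer genes were changed there than were called in the data, so these shares may understate recovery.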

Other observations

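The tests of a swap and of depth for 64 h replicate 3, of depth for 16 h replicate 2 (both depth tests replaced a first form whose outcome was fixed), of the 0 h libraries in its place and of scaling for the glycolysis genes were chosen after the result was seen, as were the fit without both libraries that stood apart and the genes given per library below.

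Further gene groups passed the camera test of limma beside those of the report. Mitochondrial ribosome genes had 20 of 61 fallen and 0 risen from 0 h to 16 h (9 fallen adjusted over the list alone; median -0.54; adjusted p = 0.0187, and adjusted p = 0.599 with an estimated correlation), with MRP8 5.45-fold lower; the fallen genes numbered 11 without 0 h replicate 1, 9 without 0 h replicate 2, 11 without 16 h replicate 1, and 13 without 16 h replicate 2, 16 h replicate 3 or 48 h replicate 3. From 0 h to 64 h 33 of them fell and 4 rose (33 and 4 adjusted over the list alone; adjusted p = 0.00267, and adjusted p = 0.508 with an estimated correlation), with MRPL40 5.08-fold lower, and 2 rose without 0 h replicate 1, 0 h replicate 2 or 64 h replicate 3. Members were matched by symbol or description, so MRP8, for one, need not belong to the mitochondrial ribosome. The genes of this list are short (median 645 bp), so the differences by gene length among the 0 h libraries touch both comparisons with 0 h. From 16 h to 32 h 10 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0169, and adjusted p = 0.599 with an estimated correlation), and the risen genes numbered 6 without 16 h replicate 1, 4 without 16 h replicate 3 or 32 h replicate 1 and 3 without 32 h replicate 2. Ergosterol and isoprenoid synthesis genes had 10 of 25 fallen and 1 risen from 0 h to 16 h (11 and 1 adjusted over the list alone; adjusted p = 0.0281, and adjusted p = 0.602 with an estimated correlation; 6 fell without 0 h replicate 3), and 13 fallen and 2 risen from 0 h to 64 h (14 and 2 adjusted over the list alone; adjusted p = 0.0138, and adjusted p = 0.589 with an estimated correlation), with ERG20, farnesyl diphosphate synthase, 33.2-fold lower. Of 20 fatty acid synthesis genes 10 fell and 2 rose from 16 h to 32 h (10 and 2 adjusted over the list alone; median -1.49; adjusted p = 0.0283, and adjusted p = 0.482 with an estimated correlation), with a long-chain acyl-CoA synthetase gene (WICANDRAFT_36592) 7.46-fold lower; 5 fell without 32 h replicate 1 or 32 h replicate 2 and 6 without 16 h replicate 3.

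Between the later time points, lists passed camera without a called member. From 32 h to 48 h the medians were -0.39 for the mitochondrial ribosome (0.05 with library size scaling; adjusted p = 1.09e-10, and adjusted p = 0.253 with an estimated correlation), -0.32 for the respiratory chain (0.13 with library size scaling; adjusted p = 0.00019, and adjusted p = 0.599 with an estimated correlation), -0.29 for arginine, lysine and histidine synthesis (0.16 with library size scaling; adjusted p = 0.00576, and adjusted p = 0.557 with an estimated correlation), -0.17 for oxidative stress defence (0.26 with library size scaling; adjusted p = 0.0448, and adjusted p = 0.582 with an estimated correlation) and 0.36 for DNA replication and histones (adjusted p = 0.000955, and adjusted p = 0.253 with an estimated correlation), with 0 genes past the threshold adjusted over the list alone in each. The log2 fold changes of this comparison had a rank correlation of 0.217 with gene length, and genes of the mitochondrial ribosome, the respiratory chain and oxidative stress defence are short (medians 645, 554.5 and 729 bp, against 1215 bp for all tested genes), so their lower medians cannot be separated from that trend. From 48 h to 64 h ribosome biogenesis had a median of -0.41 (1 risen and 1 fallen adjusted over the list alone; adjusted p = 0.000164, and adjusted p = 0.557 with an estimated correlation) and the mitochondrial ribosome one of -0.25 (0 adjusted over the list alone; adjusted p = 0.0477, and adjusted p = 0.686 with an estimated correlation). The medians of gluconeogenesis (0.67; 7 risen and 1 fallen adjusted over the list alone; adjusted p = 0.00395, and adjusted p = 0.347 with an estimated correlation), oxidative stress defence (0.47; 5 risen; adjusted p = 0.0218, and adjusted p = 0.508 with an estimated correlation), beta-oxidation (0.42; 0; adjusted p = 0.03, and adjusted p = 0.599 with an estimated correlation) and fatty acid synthesis (0.36; 5 risen; adjusted p = 0.0223, and adjusted p = 0.482 with an estimated correlation) turned negative with library size scaling (-0.12, -0.15, -0.29 and -0.34). A list meant for plant and chloroplast transcripts matched only ribosomal genes of the yeast, so its passes say nothing about RNA from apricot.

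From 0 h to 16 h further groups did not pass camera. Of 46 oxidative stress defence genes 8 rose and 10 fell (adjusted p = 0.584), with a manganese superoxide dismutase gene (WICANDRAFT_78614) from 1100 ± 496 to 16.9 ± 2.7 CPM; 5 rose without 0 h replicate 1. Of 26 iron and copper uptake genes 5 rose and 8 fell (adjusted p = 0.0887), of 39 proteasome genes 1 rose and 9 fell (adjusted p = 0.0753) and of 14 cell wall genes 2 rose and 4 fell (adjusted p = 0.222). Some transcripts differed widely among libraries of the same time point. HSP82 stood at 602, 715 and 4710 CPM at 64 h, HSP26 at 1580, 2450 and 30400 CPM, and JEN1, a carboxylic acid transporter gene, at 60.9, 20.1 and 1140 CPM; at 32 h JEN1 stood at 2950, 2330 and 94.9 CPM.

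The library of 64 h replicate 3 resembled the 32 h and 48 h libraries more than its own group, with a rho of 0.951 with 32 h replicate 2 and at most 0.836 with its own group. A swap with a 32 h or 48 h library stays open: 1 of those 6, 32 h replicate 3, correlated more with 64 h replicate 1 (0.903) than with its own group (0.886 at most), but 0 of the 6 had its highest rho with 64 h replicate 1 or 2 (a first form of this test, replaced after its result was seen). Lower depth is argued against, since 64 h replicates 1 and 2 thinned to its 17.68 M counts still had a rho of at least 0.942 with each other over 20 thinnings. A single wrong label stays open: on genes chosen without this library, its median position on a scale from 0 (32 h and 48 h) to 1 (64 h replicates 1 and 2) was 0.12, inside the -0.24 to 0.36 of the 32 h and 48 h libraries (0.36 for 32 h replicate 3). A 64 h culture that was slower may look the same, and no test here separates these.

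The library of 16 h replicate 2 stood apart from its group. A bias by gene length is argued against, since its log2 ratio to its group mates had a rank correlation of -0.013 with length, against up to 0.478 in size in the other libraries. Lower depth is argued against, since replicates 1 and 3 thinned to its 24.4 M counts still had a rho of at least 0.963 with each other over 20 thinnings (0.754 at most with replicate 2), and all 6 libraries of lower depth had a higher rho with their own group. A culture further along the time course may explain part of the difference. This library's log2 ratio to replicate 1 correlated at 0.476 with that of 32 h to replicate 3, above the 0.3 set beforehand. With replicates 1 and 3 exchanged the correlation was 0.485. Replicates 1 and 3 are much alike (rho 0.964), so both ratios share nearly the same baseline. That can raise the correlation for any library unlike them, so 0.3 is not a neutral bar. The 0 h libraries in place of this library gave 0.043 to 0.203, and 0.159 to 0.248 exchanged. Other time points in place of 32 h, which were not planned, gave 0.369 (48 h), 0.437 (64 h) and 0.085 (0 h). The glycolysis list showed no such advance, in values outside the planned tests. Its median log2 ratio of a 32 h library to 16 h replicate 2 was -4.93 to -4.74. That lies inside the -5.39 to -4.36 for 16 h replicates 1 and 3. Invertase, lower in 16 h replicate 2 than in the other 16 h libraries, went the other way. A wrong label that put a library of another sampled time point here is argued against, though by values outside the planned tests. The rho of 16 h replicate 2 was at most 0.706 with any such library, against up to 0.754 with its own group. Libraries of those time points had a rho of at least 0.759 with every member of their own group. A mixed sample, or one from outside the series, was not tested for this library.

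The fall of glycolysis genes from 16 h to 32 h was weighed against scaling and depth. With the scalings other than TMM the list's median was -3.49 or lower, which argues against a few genes that take most counts as its whole source. After thinning of every library to 1 depth 16 of the 20 genes still fell (median -4.70). Thinning keeps the expected share of counts of each gene, so it could hardly have undone falls of this size. Nothing is concluded from it about depth. A change of carbon source as sugar ran out may explain the fall, but this remains a hypothesis, since sugar levels of the broth are not given in the sources used here.

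The high level of ZRT1 and the Fe/Zn transporter gene WICANDRAFT_85399 at 0 h led to the hypothesis that zinc may have been low there. Of 11 other genes known to respond to zinc in baker's yeast, 5 fell from 0 h to 16 h (ZRT3 by log2 -3.18, MCD4 -2.65, ZRG17 -1.71, ZAP1 -2.48 and ZPS1 -5.60) and 0 rose, where 17.8% of all tested genes fell. The test had been set at 6 or more for and 2 or fewer against, so it left the hypothesis undecided.

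Other splits of the 6 libraries of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split and the highest other gave 2558 and 0 changed genes for 16 h against 0 h (1 of 10 splits with as many), 2007 and 688 for 32 h against 16 h (1), 2452 and 502 for 64 h against 16 h (1), 3312 and 0 for 64 h against 0 h (1), 0 and 2 for 48 h against 32 h (10), and 1 and 210 for 64 h against 48 h (2). In the last comparison the split with 210 genes set 64 h replicate 3 with 48 h replicates 1 and 3, which points to a structure of the samples other than the time point. For 32 h against 16 h the split with 688 genes set 32 h replicate 3 with 16 h replicates 1 and 3. For 64 h against 16 h the split with 502 genes set 64 h replicate 2 with them. Both placed 16 h replicate 2 with libraries of the later time point. Of 100 groupings of the 15 libraries into 5 groups of 3, only the real one (1) gave as many genes changed over time (4336, highest other 822). That share is the lowest 100 groupings can give, so chance is argued against for that count but not excluded. Nor does the test separate time from anything else that libraries of a time point shared. For the 54 list tests that passed, 22 of 100 groupings gave as many (highest other 69), so chance cannot be excluded for their number.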
